A study of Mus musculus with 2 samples.

How the data were processed

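Non-cardiomyocytes of hearts from male C57BL6/J wild-type mice were profiled on day 20 after sham or TAC surgery, with 1 library per group. Per the labels, hearts were cleared of blood and digested with collagenases and a protease, the suspension was filtered, cardiomyocytes settled by gravity, red cells were lysed, debris was removed, and DAPI-negative viable cells were sorted before droplet capture with a Chromium Next GEM kit, on 1 lane per group. The deposited matrices hold raw UMI counts per gene and barcode, made with Cell Ranger 3.1.0 per the file headers, for barcodes already called as cells. Per the submitters' processing notes the genome build was mm10 and Seurat was among their tools; its role, the gene annotation and the sequencing settings are not given in the sources used here. Whole-number values and unlike totals between barcodes were checked in the files. Of 31053 gene IDs, 31011 matched the GENCODE vM21 annotation, from which chromosome, start and end were taken. The authors' names of cells were not used here; all names were rebuilt, and differences from other work on these cells can come from that.

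Barcodes with fewer than 500 genes, fewer than 1000 UMIs or over 15% mitochondrial UMIs were left out, 462 in the sham and 901 in the TAC library. Doublets were called per library with Scrublet in Scanpy 1.11.5 at an expected rate of 0.07, falling back to the top 7% of scores where under 0.5% were called; 70 sham cells (0.879%) and 146 TAC cells (1.83%) were removed. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes chosen per library and combined, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (igraph 0.11.9, seed 7) gave clusters over both libraries without integration. A cluster took the name of the marker class with the highest mean scaled log2(CPM + 10) of its markers, out of 21 marker classes, if the score reached 0.6, at least 3 markers were seen in 20% of cells, no class of another lineage reached 0.55 and no class of its own lineage came within 0.05. Clusters that failed were clustered again at resolution 0.5. A name was withdrawn where the 10 leading genes held more markers of another class, or where the median depth was under the library's by a divisor of 3 with no own marker leading. Haemoglobin genes did not count as a second lineage, and in alternatives a cluster of at least 100 cells lost its name only for 3 or more foreign markers.

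UMIs were summed per class and library and given as CPM, and log2 ratios TAC/sham used CPM + 1. A gene with 0 UMIs in a library was bounded with a floor of 3 counts in the class sum. With 1 library per group no test was made, and no p-value was computed from cells. Classes were first planned for comparison at 200 cells or more per library, which fibroblasts and macrophages met; endothelial and lymphatic endothelial cells were added at a minimum of 70 after the data were seen. Genes were named by size: in each class the 10 largest log2 ratios in each direction, or 5 in lymphatic endothelial cells, among genes with at least 50 CPM and seen in at least 10% of cells in at least 1 library, and, in the library where they were higher, not under 10% of their CPM in another class of at least 50 cells, a limit against free RNA. Mitochondrial, ribosomal protein, haemoglobin and Y-linked genes, Xist and unnamed gene models were left out. A few genes that the rule names are not reported here. Up to 4 members of each list were named as well, by the size of their ratio. The rule, 33 gene lists, the marker classes, the comparisons and the alternatives were written before the data were examined.

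A list was measured over members with at least 10 CPM in either library, given at least 4 of them. Its median log2 ratio carries an exact 95% interval over members and was set against 10000 random lists matched in 20 bins of mean log2 CPM, as a description. With fewer than 6 members the interval was the full range of the members, which covers less than 95%. A list was reported in a class if at least 50% of measured members passed the free-RNA limit, a choice made after the values were seen; haemoglobin RNA in all classes and collagens in macrophages were reported regardless. This left 30 lists in fibroblasts, 25 in macrophages, 28 in endothelial and 27 in lymphatic endothelial cells. In 6 cases a list gene was matched through an older symbol, such as Ctgf for Ccn2. For shares of cells with a UMI, 12 genes were compared after thinning each cell to the 20th percentile of depth of the shallower library, rounded down to a step of 100, and shallower cells were left out. Fibroblast, macrophage and endothelial classes were also clustered alone at resolution 0.5.

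The steps for ratios, intervals and random lists were run on simulated class sums, with 200 changed genes per class. Counts were drawn with Poisson error only, from the pooled sums of both libraries, and read for genes at 50 CPM or more. They held no variation between cells or mice and no free RNA, and clustering, naming and thinning were not simulated. The values that follow thus check these steps under counting error alone. Fold changes came within 0.5 log2 units of the truth for 100% of changed genes in fibroblasts and macrophages, 88% to 96% per fold in endothelial and 84% to 94% in lymphatic endothelial cells, and intervals held the truth for 90% to 100%. Of 200 lists of unchanged genes per class, 3% to 6% fell outside the middle 95% of random lists.

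The alternatives set in advance were a stricter filter (1000 genes, 10% mitochondrial UMIs), no cell filter, doublets kept, resolutions 0.5 and 2.0, libraries clustered separately, median-of-ratios scaling, equal weight per cell, cells thinned to equal depth, CPM + 10, other CPM minimums, lists without free-RNA members, no thinning or a smaller thinned depth, and sub-cluster resolutions 0.3 and 1.0. Shares among named cells that are not fibroblasts, and macrophage and endothelial sums and macrophage background shares without sub-clusters led by fibroblast genes, were added after seeing the data. For a closing test, the last 400 bases of coding transcripts were searched for words of 25 bases found in processed pseudogenes. For the tests of pseudogene copies and of the daily clock, the spread of the members was added to the rule for reading them after the values were seen. It left undecided tests that the rules first written would have counted against the explanation. Python 3.11.15, AnnData 0.12.19, scikit-learn 1.9.0, SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 were used.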

Results

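Single-cell RNA was measured in the non-cardiomyocyte fraction of hearts from male C57BL6/J wild-type mice on day 20 after sham surgery or transverse aortic constriction (TAC), an operation that narrows the aorta and loads the left ventricle with pressure. Each group was 1 library, and the number of hearts behind a library is not given in the labels, so no difference below has a replicate check and no test was made. The sham library held 8426 barcodes with 42490230 UMIs (unique molecular identifiers, each 1 counted RNA molecule), and the TAC library 8901 barcodes with 96003109 UMIs. After filtering, 7894 sham cells and 7854 TAC cells were kept. Their median depth was 4881.5 UMIs and 2104.5 genes per cell in the sham library and 11158 UMIs and 3540 genes in the TAC library. Values within a cell class are UMIs summed over its cells as counts per 1e6 UMIs of the class (CPM), with exact Poisson 95% intervals for sums and exact conditional intervals for ratios. Shares carry exact Clopper-Pearson 95% intervals. All intervals cover counting error only, not differences between mice.

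The first comparison asked which non-cardiomyocyte classes made up each library, since pressure overload is known to draw in immune cells and to enlarge the fibroblast and vessel compartments. Fibroblast-like cells were the main class in both, at 77.2% of sham cells (76.3 to 78.2) and 68.6% of TAC cells (67.5 to 69.6). Endothelial-like cells were 1.57% (1.31 to 1.87) of the sham library and 7.65% (7.07 to 8.26) of the TAC library, a share 4.87-fold higher (4.01 to 5.96). Lymphatic endothelial-like cells were 0.912% (0.714 to 1.15) and 4.09% (3.66 to 4.55), a 4.48-fold higher share. Neutrophil-like cells, which reach injured heart from blood, were 3 of the sham cells and 76 of the TAC cells, 0.0380% and 0.968%. Macrophage-like cells had a lower share in the TAC library, 12.05% (11.3 to 12.8) against 8.09% (7.49 to 8.71), a ratio of 0.671 (0.606 to 0.743). Pericyte-like cells were 0.570% and 1.04%, while B cell-like cells numbered 51 in each library. Endocardial-like cells were 47 and 54, a ratio of 1.15 that was between 0.481 with libraries clustered separately and 9.94 with no cell filter, so no direction is given. Cells without a name were 6.16% of the sham library and 7.77% of the TAC library. Several clusters among them scored highest for macrophages but were mixed with another class or led by its markers. The largest held 105 and 114, 68 and 37, 10 and 90, and 14 and 75 sham and TAC cells. The macrophage ratio thus depends on the naming rule. All shares here were set after enzymatic digestion, gravity settling and a viability sort, each of which can recover classes unequally, so they are shares of sorted cells and not of the heart. Among named cells that were not fibroblasts, a denominator chosen after the shares were seen, macrophage-like cells were 72.5% and 34.2% and endothelial-like cells 9.46% and 32.3%. The neutrophil ratio of 25.5 (8.39 to 126) rested on 3 sham cells and was 4.66 with no cell filter, and the endothelial ratio was 7.62 with the stricter filter.

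**Figure D1:**
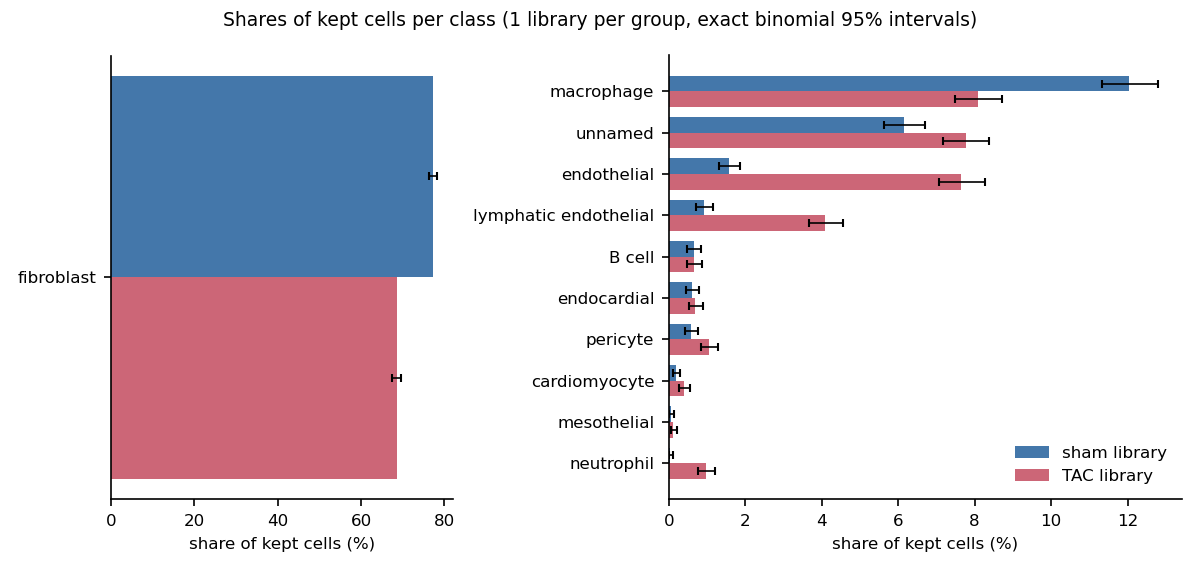
Share of kept cells (%) per class named from markers in the sham and the TAC library, with fibroblasts on their own axis; bars are shares and lines exact binomial 95% intervals. Endothelial-like cells were 1.57% and 7.65%, macrophage-like cells 12.05% and 8.09%.

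The second comparison asked how gene expression within fibroblast-like cells differed, since cardiac fibroblasts under pressure overload are known to take on a matrix-producing state. Genes of that state led the list of larger values in the TAC library. Thrombospondin 4, Thbs4 (ENSMUSG00000021702, mm10 chromosome 13, 92751590 to 92794818), was at 1.25 CPM in the sham library and 162 CPM in the TAC library, 129.9-fold higher (94.97 to 183). Cartilage oligomeric matrix protein, Comp (ENSMUSG00000031849, chromosome 8, 70373558 to 70382066), was at 6.91 and 490.2 CPM. Periostin, Postn (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037), was at 45.2 and 1337 CPM, 29.6-fold higher (28.1 to 31.2). Cilp was at 33.2 and 515.5 CPM, and Ctgf, a target of TGF-beta and of stretch, at 273 and 2781 CPM. Ltbp2, Timp1, Prg4 and Mfap4 followed with log2 ratios between 3.06 and 3.68. The eosinophil-attracting chemokine Ccl11 (ENSMUSG00000020676, chromosome 11, 82057823 to 82062955) had the largest lower value, 168 CPM in the sham library and 5.36 in the TAC library, 31.4-fold lower (28.2 to 35.1). Inmt, at 256 and 16.6 CPM, Alkal2, Efemp1, Scara5 and Ackr3 were 6.51-fold to 16.6-fold lower, and Gadd45g, Ccl7, Socs3 and Htra1 were 5.18-fold to 6.33-fold lower. In the 6097 sham and 5385 TAC fibroblast-like cells, none of the genes that the size rule named moved by more than 1.5-fold under any alternative other than the larger pseudocount. Without thinning, Thbs4 was seen in 13.9% and Postn in 81.4% of TAC cells of this class. Thbs4 and Comp also led a fibroblast sub-cluster of 8 sham and 1131 TAC cells. The mix of fibroblast states is thus not separated from expression per cell.

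**Figure D2:**
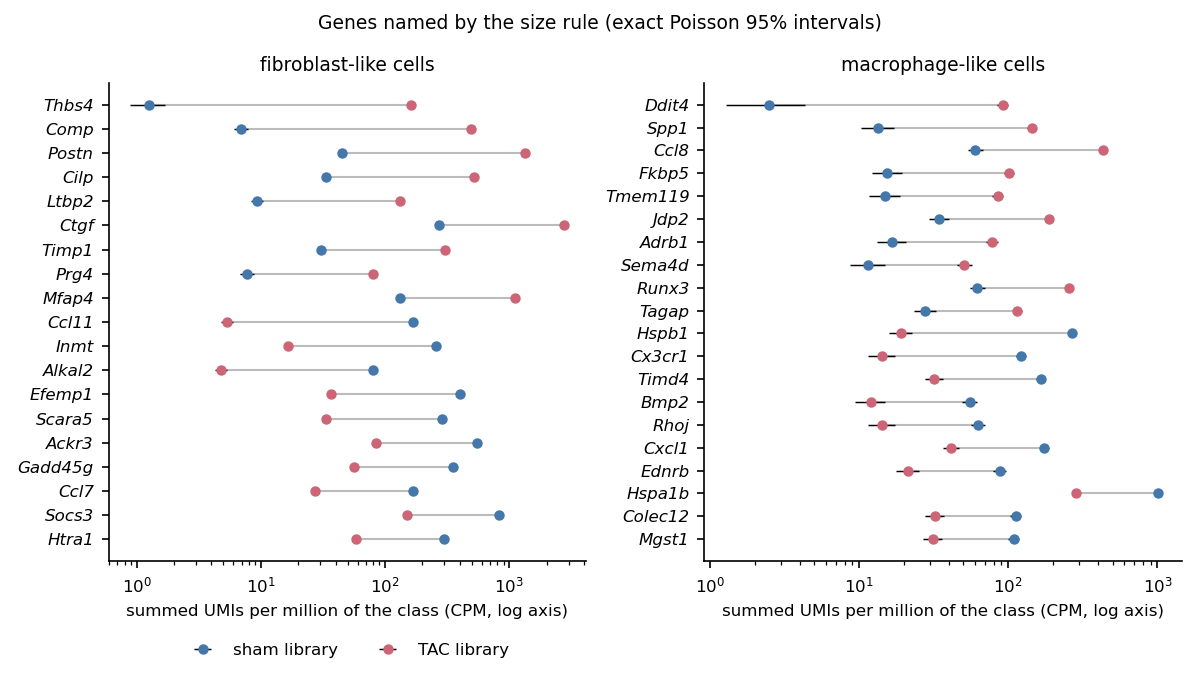
Summed UMIs of the class in CPM (log axis) of genes named by the size rule in fibroblast-like and macrophage-like cells of the sham and the TAC library; points are class sums and lines exact Poisson 95% intervals. In fibroblast-like cells Thbs4 was at 1.25 and 162 CPM and Ccl11 at 168 and 5.36 CPM.

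Lists of matrix and activation genes in fibroblast-like cells went the same way as many of these single genes. Of 15 measured fibrillar and network collagens, 10 were at least 2-fold higher in the TAC library and the median log2 ratio was 1.12 (0.77 to 1.78), led by Col8a1 at 2.01 and, beside the naming marker Col1a1, Col16a1 at 1.59. Matricellular and elastic matrix proteins had a median of 0.97 (0.32 to 2.58), with 12 of 26 members at least 2-fold higher and 1 lower. Fibroblast activation regulators had a median of 1.01 (0.39 to 2.20), and among them the transcription factor Meox1 was at 99.3 and 733 CPM. Myofibroblast contractile genes had a smaller median of 0.55 (0.06 to 1.81), with 3 of 13 members at least 2-fold higher, among them Actn1 at 2.45. Genes of quiescent fibroblasts were lower in the TAC library, with a median of -0.80 (-3.07 to -0.18). Lists of interferon response (0.39, led by Isg15 at 1.57) and of glycolysis and hypoxia (0.33, led by Gapdh at 1.56) were higher. Immediate early genes (-0.70) and heat shock genes (-0.54), which digestion of tissue is known to raise, were lower, although Egr2 at 1.83 and Nr4a2 at 1.53 went the other way. The medians of these lists lay outside the middle 95% of 10000 matched random lists, which was between -0.25 and 0.27 for the collagens. TGF-beta genes, with a median of 0.45, collagen processing genes (0.54), mesenchymal transition genes (0.70), proteoglycans (0.25) and basement membrane genes (0.24) lay above random lists too, but with intervals over members that included 0. Within those, Tgfb1 at 2.12, Lox at 1.85, Fn1 at 1.61, Bgn at 1.44 and Col4a2 at 1.84 were higher, while P4ha2 at -1.03 was lower. Genes of matrix proteases and their inhibitors, MHC class I, the unfolded protein response, the cell cycle and the chemokine list had medians within those of random lists, at -0.10, 0.06, -0.02, -0.05 and -0.16, so Timp1, Ccl11 and Ccl7 did not stand for their lists.

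**Figure D3:**
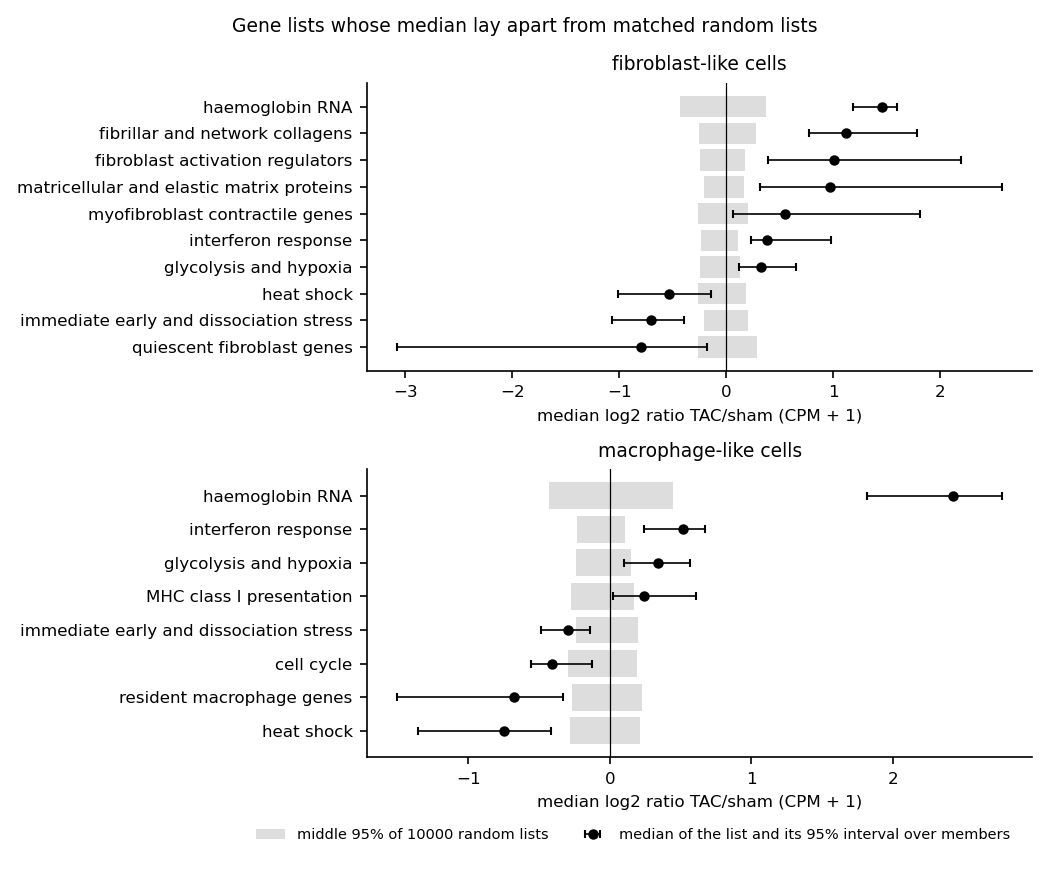
Median log2 ratio TAC/sham (CPM + 1) of gene lists that lay apart from matched random lists in fibroblast-like and macrophage-like cells; points are list medians, lines their 95% intervals over members and grey bars the middle 95% of 10000 random lists. In fibroblast-like cells collagens stood at 1.12 and quiescent fibroblast genes at -0.80. The haemoglobin median of 1.45 was -1.24 when the libraries were clustered separately. Haemoglobin lines, over 4 members, are the full range of the members and not 95% intervals.

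Shares of fibroblast-like cells with at least 1 UMI of an activation gene were compared at equal depth, because TAC fibroblasts held a median of 12093 UMIs and sham fibroblasts 4980.0. Each cell was thinned to 3800 UMIs, which left out 1164 sham and 225 TAC cells. Postn was seen in 4.16% of sham cells (3.62 to 4.75) and 68.3% of TAC cells (67.0 to 69.5). Meox1 was seen in 22.4% and 75.8%, Cilp in 4.97% and 49.9%, and Comp in 1.30% and 21.3%. The myofibroblast gene Acta2 was seen in 1.68% and 6.18% of cells, and Cthrc1, a gene of matrix-producing fibroblasts in scars, in 0.142% and 3.97%. Without thinning the TAC shares were 81.4% for Postn, 91.0% for Meox1, 64.1% for Cilp, 28.4% for Comp, 13.8% for Acta2 and 7.61% for Cthrc1, and the sham shares 4.38%, 25.8%, 5.76%, 1.49%, 2.17% and 0.180%. Macrophage-like cells, which should lack these genes, gave the background at the same thinning and at median depths of 4324 and 8390 UMIs. There Postn was seen in 0.487% of sham and 6.40% of TAC cells, Meox1 in 2.27% and 4.21%, Cilp in 0.812% and 3.37%, and Acta2 in 0.974% and 0.505%. Comp was seen in 0 of 616 sham macrophage-like cells and in 2.36% of TAC cells, and Cthrc1 in 0 of 616 and in 0.168%. The floor of 3 counts equals a share of 0.487% in those sham cells, which is not an exact upper limit. Of the sham macrophage-like cells, 7.36% lay in a sub-cluster led by fibroblast genes, against 0.787% of TAC cells. Without that sub-cluster the sham background was 0.548% for Meox1, 0.183% for Cilp and 0.914% (0.297 to 2.12) for Acta2, and Cthrc1 was seen in 0 of 547 cells. The sham shares of Acta2 and Cthrc1 in fibroblast-like cells were not told apart from either background at this depth, and the TAC shares of all 6 genes lay above both.

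**Figure D4:**
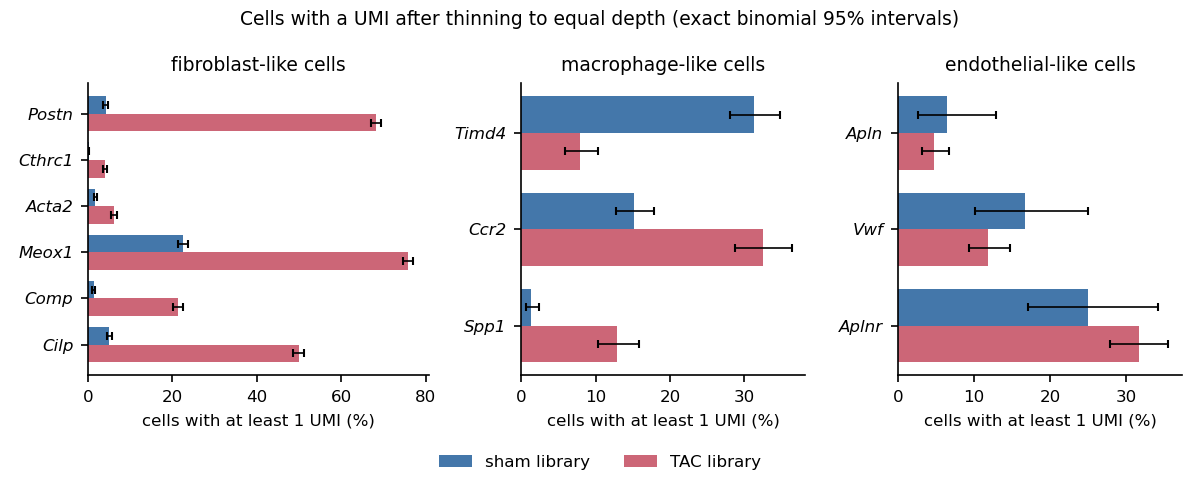
Share of cells with at least 1 UMI (%) after thinning to equal depth in fibroblast-like, macrophage-like and endothelial-like cells of the sham and the TAC library; bars are shares and lines exact binomial 95% intervals. Postn was seen in 4.16% and 68.3% of fibroblast-like cells and Timd4 in 31.4% and 7.83% of macrophage-like cells.

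The third comparison asked how macrophage-like cells differed, since resident cardiac macrophages are known to be partly replaced by cells from monocytes after injury. Timd4, a gene of resident macrophages (ENSMUSG00000055546, chromosome 11, 46810800 to 46844332), was at 165 and 31.8 CPM, 5.17-fold lower in the TAC library (4.42 to 6.08), and the fractalkine receptor Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879) at 122 and 14.2 CPM, 8.59-fold lower (6.86 to 10.9). The list of resident macrophage genes had a median of -0.68 (-1.50 to -0.33), with Ccl24 at -1.74 and Folr2 at -1.35. Osteopontin, Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), was at 13.4 and 144 CPM, 10.7-fold higher (8.31 to 14.0), and the monocyte chemokine Ccl8 at 60.1 and 432 CPM. The stress gene Ddit4 (ENSMUSG00000020108, chromosome 10, 59949669 to 59951834) was at 2.48 and 91.9 CPM, 37.1-fold higher (21.1 to 72.2). Fkbp5, Tmem119, Jdp2, Adrb1, Sema4d, Runx3 and Tagap were 4.10-fold to 6.56-fold higher. The heat shock gene Hspb1 was at 266 and 19.1 CPM, and Bmp2, Rhoj, Cxcl1, Ednrb, Hspa1b, Colec12 and Mgst1 were 3.50-fold to 4.61-fold lower. These sums include a sub-cluster led by fibroblast genes, of 70 sham and 5 TAC cells. Genes that fibroblasts also express can read lower in the TAC library through it. Some alternative other than the larger pseudocount moved 7 of the 20 genes that the size rule named in this class by more than 1.5-fold. The log2 ratio of Spp1, 3.33, was 4.41 and that of Ccl8, 2.82, was 2.12 at equal depth, and that of Cxcl1, -2.05, was -1.23 with doublets kept. With no cell filter, where 672 and not 70 sham doublets were removed as well, Hspb1 at -3.73 was -3.02, Sema4d at 2.05 was 1.45, Rhoj at -2.07 was -0.47 and Mgst1 at -1.77 was -0.43.

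Timd4, Ccl24, Folr2 and Ednrb also led a macrophage sub-cluster named resident, of 374 sham and 3 TAC cells, and Cx3cr1 led a larger one named for MHC class II, of 452 sham and 24 TAC cells. Sub-clusters without a name held 92.1% of TAC and 11.6% of sham macrophage-like cells. The largest of them, of 20 sham and 374 TAC cells, scored highest for MHC class II, but no such marker was among its leading genes. The named counts thus do not show that TAC cells lacked these types. At sub-cluster resolution 0.3 Cx3cr1, Ccl24 and Timd4 led the same sub-cluster. The mix of macrophage types is thus not separated from expression per cell. Interferon response genes were higher in TAC macrophage-like cells, with a median of 0.52 (0.24 to 0.67), led by Irf7 at 1.40 and Ifi27l2a at 1.34. MHC class I genes had a median of 0.24 (0.02 to 0.61) and glycolysis and hypoxia genes of 0.34 (0.10 to 0.57), with Gapdh at 1.60. Heat shock genes (-0.75), immediate early genes (-0.30) and cell cycle genes (-0.41) were lower. Genes of MHC class II and of monocyte-derived macrophages had medians of -0.04 and 0.04, within random lists, although Ccr2, a receptor of cells from monocytes and a marker of the monocyte class here, was higher by 1.00. A cluster of 105 sham and 114 TAC cells, led by genes such as Ccr2, H2-Ab1 and Cd209a, was left without a name. Its cells are not in these sums, so both medians hold for the named class only. Chemokines had a median of -0.44 and went both ways, with Ccl2 at -1.43 and Ccl12 at 1.21. Genes of lipid and scar associated macrophages had a median of 0.22, with Trem2 at 0.75 and Lpl at -1.16. After thinning to 3100 UMIs, which left out 170 sham and 35 TAC cells, Timd4 was seen in 31.4% of sham and 7.83% of TAC macrophage-like cells, Ccr2 in 15.1% and 32.5%, and Spp1 in 1.28% and 12.8%. Without thinning these shares were 35.3% and 14.0%, 15.9% and 40.3%, and 2.10% and 20.8%, at median depths of 4324 and 8390 UMIs. In fibroblast-like cells thinned alike, at median depths of 4980.0 and 12093, Spp1 was seen in 0.0362% and 2.15% and Ccr2 in 0.109% and 0.211%. Timd4 was seen there in 0.145% of sham cells and in 0 of 5207 TAC cells. The floor of 3 counts equals 0.0576% of those TAC cells, which is not an exact upper limit. Collagens in macrophage-like cells had a median of -1.43, but 1 of 12 members passed the free-RNA limit, and without a sub-cluster led by fibroblast genes, 70 of 951 sham and 5 of 635 TAC cells, the median was 1.37.

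The endothelial-like class, 124 sham and 601 TAC cells, was smaller than the 200 cells per library first planned, so its comparison was added after the data were seen and its intervals are wide. The retinol-binding protein gene Rbp7, known from heart capillaries (ENSMUSG00000028996, chromosome 4, 149449687 to 149454978) was at 417 and 2902 CPM, 6.95-fold higher (5.799 to 8.41), and Lrg1, a secreted glycoprotein gene that acts on TGF-beta signals in vessels (ENSMUSG00000037095, chromosome 17, 56119678 to 56122001), at 24.8 and 403 CPM, 16.3-fold higher (7.88 to 40.6). Ddit4 had 2 UMIs in the sham library and 972 in the TAC library, 46.2-fold higher in CPM (12.7 to 382), and Tmem252 had 0 and 186, at least 5.89-fold higher against a floor of 3 counts in the sham sum. Fam167b, Cops9, Cldn15 and Babam2, each with 1 or 2 sham UMIs, and Il4ra and Gapdh made up the other higher genes. Gja4, a connexin gene of arterial endothelium, was at 138 and 23.2 CPM, 5.95-fold lower (3.91 to 8.94), and the endothelin gene Edn1 at 124 and 21.2 CPM. Rbp7, which was higher, and Gja4 are both on the marker list used here to name arterial-like sub-clusters. Adk, Alpl, Cystm1, Pir, Gadd45g and Prdm16 were 4.33-fold to 5.37-fold lower. Cytl1 at -2.97, also a marker used to name endocardial cells, was lower as well, but 0.35 when the libraries were clustered separately. These values do not separate the mix of endothelial subtypes from expression per cell. An arterial-like sub-cluster led by genes such as Gja4, Alpl and Hey1 held 20.2% of sham (13.5 to 28.3) and 8.49% of TAC cells (6.38 to 11.0), and a capillary-like one, 93.6% of whose cells were from the TAC library, held 14.5% and 44.1%, shares that were 30.6% and 61.1% at sub-cluster resolution 0.3 and 3.23% and 21.3% at 1.0. The haemoglobin genes Hba-a1 and Hbb-bs were among the leading genes of this capillary-like sub-cluster, but not of that at resolution 0.3. The share of the former is thus not separated from haemoglobin RNA. Some alternative other than the larger pseudocount moved 16 of the 20 genes that the size rule named in this class by more than 1.5-fold. Cops9 at 3.46 was 1.56 and Babam2 at 2.91 was 1.27 at clustering resolution 0.5, Il4ra at 2.33 was 1.32 at equal depth, and Cystm1 at -2.27 was -0.94 and Pir at -2.20 was -1.44 with libraries clustered separately.

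Fatty acid uptake genes, a trait of heart capillaries, had a median of 0.49 (0.05 to 1.08) in endothelial-like cells, with Gpihbp1 at 1.11 and Pparg at 1.08. Fabp5 at 0.70 was -0.79 at clustering resolution 0.5. As for the single genes, list values here are not separated from the mix of capillary-like and arterial-like cells given above. Interferon response genes had a median of 0.43 (0.12 to 0.93), led by Oasl2 at 1.68 and Irf7 at 1.62, and glycolysis and hypoxia genes of 0.59 (0.01 to 0.89). Heat shock genes (-0.74) and immediate early genes (-0.59) were lower, as in fibroblast-like cells. Angiogenesis genes had a median of 0.15 and went both ways, with Trp53i11 at 0.95 and the Notch genes Hey1 at -1.59 and Notch1 at -0.91. Activation and adhesion genes had a median of -0.31, with Vcam1 at -1.13. After thinning to 1300 UMIs, which left out 16 sham and 8 TAC cells, Apln was seen in 6.48% and 4.72%, Vwf in 16.7% and 11.8%, and Aplnr in 25% and 31.7% of cells, differences whose intervals included 0 and that were not detectable at this depth. Without thinning, at median depths of 1886 and 4311 UMIs, the shares were 7.26% and 12.3%, 24.2% and 19.8%, and 33.9% and 56.6%. In fibroblast-like cells thinned alike each of these genes was seen in at most 0.0935% of cells.

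Lymphatic endothelial-like cells, 72 in the sham and 321 in the TAC library, were also compared only after the data were seen. Serpina3n, an acute-phase protease inhibitor gene (ENSMUSG00000021091, chromosome 12, 104406729 to 104414329), had 4 sham and 904 TAC UMIs, 19.4-fold higher in CPM (7.55 to 71.4). Lrg1 was at 216 and 2098 CPM, 9.73-fold higher (7.35 to 13.2), and Ddit4, Cmah and Ttyh1, each with 1 or 2 sham UMIs, were higher by 4.15, 3.45 and 2.87 on the log2 scale. Heat shock genes were lower, with Hspa1a at 348 and 29.8 CPM, Hspa1b at 765 and 131, and Hspb1 at 439.9 and 99.3, and their list had a median of -0.55 (-2.13 to -0.28). The shares of cells with a UMI, without thinning, were 11.1% and 11.5%, 40.3% and 36.4%, and 43.1% and 40.2%. Median depths were 2710 UMIs in the sham and 7844 UMIs in the TAC library, so these shares are not compared between libraries. The sham Hspa1a sum was 79 UMIs in 11.1% of 72 cells. Hspa1a at -3.50 was -2.10 with the stricter filter. Fam213b and Itih5 were 4.99-fold and 4.75-fold lower. Glycolysis and hypoxia genes had a median of 0.65 (0.48 to 1.42), with Gapdh at 2.18 and Eno1 at 1.49, and basement membrane genes of 0.47 (0.02 to 0.97), with Agrn at 1.496 and Col18a1 at 1.12, which were 0.63 and 0.34 at equal depth. Interferon response genes, at -0.09, and immediate early genes, at -0.06, had medians within random lists in this class. Median-of-ratios scaling took out a shift of -0.12 on the log2 scale in this class, so ratios were higher by that amount under it, and some alternative other than the larger pseudocount moved 7 of its 10 named genes by more than 1.5-fold.

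The libraries also differed in traits that bear on all of these values. Haemoglobin RNA, which comes from red cells, was higher in the TAC library in every compared class, except that its list median in fibroblasts was -1.24 when the libraries were clustered separately, where that in endothelial-like cells was 1.90 and not 5.64. It was at 71.1 and 192 CPM in fibroblast-like, 443 and 2156 in macrophage-like, 131 and 6558 in endothelial-like and 154 and 2969 in lymphatic endothelial-like cells. Cardiomyocyte genes summed to 38.6 and 55.7 CPM in fibroblast-like cells and to 109.9 and 119 CPM in macrophage-like cells. Median mitochondrial shares of UMIs were 3.11% and 3.33% in fibroblast-like and 4.62% and 5.56% in macrophage-like cells. Most fibroblast-like cells of the libraries fell into different clusters, with 1769, 1960 and 1150 sham cells in clusters of 20, 15 and 46 TAC cells, and 1807, 1033 and 1981 TAC cells in clusters of 31, 25 and 106 sham cells. Macrophage-like cells split likewise, with 888 sham and 52 TAC cells in one cluster and 63 and 583 in another, while 109 sham and 584 TAC endothelial-like cells and all lymphatic endothelial-like cells shared a cluster. Clustered within their class, 94.0% of fibroblast-like cells (93.5 to 94.4), 96.4% of macrophage-like cells (95.4 to 97.3) and 43.7% of endothelial-like cells (40.1 to 47.4) lay in sub-clusters of which at least 90% of cells came from 1 library. The endothelial-like class itself held 124 sham and 601 TAC cells, so its sub-clusters pass this limit more easily than those of the other classes. A sub-cluster mostly of 1 library may be a state or the library itself. The sub-cluster sizes given above are thus not read as changes in cell states.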

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

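The denominator without fibroblasts and the sums and background shares without sub-clusters led by fibroblast genes were tests chosen after the data were seen; the others were planned. Over the alternatives that gave a value, a direction turned in 2 of 1701 values for named genes, 5 of 1463 for list medians and 0 of 69 for share ratios. These totals hold all values, but a turn was counted only where the main interval had excluded no difference. Lists also had to lie outside random lists, which held for 10 of 30 in fibroblasts, 9 of 25 in macrophages, 6 of 28 in endothelial and 4 of 27 in lymphatic cells. The counts of turns are thus not rates of stability. Of all values, 1373, 1435 and 53 stayed within the counting or member interval. The endocardial share ratio of 1.15, whose interval included 1, was 8.21 at resolution 0.5, 7.11 with doublets kept, 9.94 with no filter, 0.765 at resolution 2.0 and 0.481 with libraries clustered separately. With libraries clustered separately, Cytl1 in endothelial cells turned to 0.35 and haemoglobin RNA in fibroblasts to -1.24 and was 1.90 in endothelial cells, while in macrophages interferon response was 0.67 and cell cycle genes -0.89. At clustering resolution 0.5 Fabp5 in endothelial cells turned to -0.79 and the endothelial share ratio was 3.74. Collagens in macrophages turned to 1.09 with doublets kept, 0.40 with the stricter filter, 1.202 with no filter and 1.37 without sub-clusters led by fibroblast genes. The stricter filter gave an endothelial share ratio of 7.62. No filter gave share ratios of 0.779 for macrophages and 4.66 for neutrophils, and medians of 1.90 and 3.33 for haemoglobin RNA in fibroblasts and macrophages and -0.59 for cell cycle genes in macrophages. Under the stricter filter and no filter the fallback rule also removed 568 and 672 sham doublets, not 70, so these values carry at least 2 changes at once. Every alternative with other clusters also used the looser limit on foreign markers for clusters of at least 100 cells. Its values thus do not stand for the named setting alone. Among named cells that were not fibroblasts the ratios were 3.42 (endothelial), 3.14 (lymphatic), 17.9 (neutrophil) and 0.471 (macrophage). Of 12 macrophage background shares, 2 moved without the fibroblast-led sub-cluster, sham Meox1 to 0.548% and sham Cilp to 0.183%. With CPM + 10 haemoglobin RNA in fibroblasts was 0.91. The cause was not tested, except that the last denominator leaves out the most numerous class. Genes at 2-fold or more, a description of size with no test, were 126 higher and 97 lower in fibroblasts, 67 and 105 in macrophages, 124 and 164 in endothelial and 178 and 217 in lymphatic cells. At 20 CPM they were 196 and 154, 122 and 215, 340 and 464, and 466 and 534, and at 100 CPM 78 and 56, 38 and 49, 57 and 69, and 89 and 82, since fewer or more genes were counted. Lower genes in macrophages were 51 with doublets kept, 56 with the stricter filter and 44 with no filter, and higher genes in endothelial cells 201 with the stricter filter. At equal depth they were 213 and 264 in endothelial and 310 and 338 in lymphatic cells. Median-of-ratios scaling moved the split to 147 and 83, 82 and 93, 145 and 138, and 232 and 158. Cells in sub-clusters of 1 library were, at resolutions 0.3 and 1.0, 94.7% and 91.8% of fibroblasts, 100% and 87.2% of macrophages and 55.9% and 48.3% of endothelial cells. Some classes were missing in separate clustering or under the stricter filter, and 96 of 110 list medians had a value at 50 CPM and 104 without free-RNA members. Depth limits the endothelial classes most, where 3 sham counts equal 10.6 CPM and 13.2 CPM. No paired analysis was possible because each group holds 1 library.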

Other observations

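The tests of the lymphatic glycolysis list and both tests of free haemoglobin RNA were chosen after the result was seen. The other tests with a prediction were set before. Genes with pseudogene copies taken without ribosomal protein genes, and list medians in further classes, had no prediction. By the rules first written, the tests of copies, of the fibroblast glycolysis list and of the clock went against their explanations. The spread of members, added to those rules after the values were seen, left each of them undecided. Some genes of fibroblast-like cells that fell in lists without a common direction differed as well. The netrin receptor gene Unc5b was higher in the TAC library at 2.46, complement C4b at 2.88 and Igfbp7 at 1.04, while the growth factor gene Pgf was lower at -2.21, thrombomodulin Thbd at -1.66 and the aggrecanases Adamts1 and Adamts5 at -1.48 and -1.18. Macrophage-like cells had C4b higher at 1.90 and Cd36 lower at -1.58. Ribosomal protein genes stayed within random lists, at 0.13 in fibroblast-like, 0.04 in macrophage-like, -0.07 in endothelial-like and 0.15 in lymphatic endothelial-like cells.

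Glycolysis and hypoxia genes were higher in the TAC library in all 4 compared classes, among them Gapdh, of whose searched sequence words 95.2% also occur in processed pseudogenes. Genes with such copies over at least 50% of the words lay above random lists in 3 of 4 classes. In endothelial cells they lay within them, at 0.083 against an upper bound of 0.095. With ribosomal protein genes left out, fibroblasts at 0.104 and macrophages at 0.085 stayed above upper bounds of 0.077 and 0.078. Lymphatic cells at 0.05 then lay within random lists, as endothelial cells at 0.09 still did, with an upper bound of 0.11 in both. Intervals over members were too wide to exclude reads shared with copies and counted unequally, which remain a candidate explanation. Without any gene that shares words the list median was 0.29 in fibroblasts, 0.27 in macrophages, 0.34 in endothelial and 0.55 in lymphatic cells, each above the upper random bounds of 0.15, 0.17, 0.24 and 0.25. The interval over members lay above that bound only in lymphatic cells (0.47 to 0.86), so copies did not account for the whole list there, while in fibroblasts it was too wide to tell (-0.25 to 0.65), and a change of metabolism with TAC stays untested.

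Ddit4 was higher by 2.33, 4.74, 5.34 and 4.15 and Fkbp5 by 1.01, 2.64, 2.09 and 1.66 in fibroblast-, macrophage-, endothelial- and lymphatic-like cells, and both are known targets of glucocorticoids and of the daily clock. A set of 9 other glucocorticoid targets had medians of 0.79 in fibroblasts and 0.68 in macrophages, both above random lists, and of 0.75 in endothelial and 0.33 in lymphatic cells, the last within random lists. The medians in fibroblasts and macrophages go with more glucocorticoid signal in the mice of the TAC library, but single targets differed. Zbtb16 was lower at -1.28 in fibroblasts and at -1.88 in lymphatic cells, and Errfi1 at -0.48 in macrophages. Zbtb16 in endothelial cells, at -1.04, had a counting interval that included no difference. In lymphatic cells Tsc22d3 was at -0.06 and Sgk1 at -0.12. The median of the Dbp phase minus that of the Arntl phase was -0.27 in fibroblasts, with members too spread to exclude a difference in the hour of collection. In macrophages the Dbp phase lay below random lists at -1.15 (full range -1.63 to -1.05 over 4 members). The Arntl phase there lay below them at -0.68, but over 3 members, under the 4 required of other lists. Its members ranged from -0.88 to 0.75, and Nfil3 was higher at 0.75. In endothelial cells the Arntl phase lay below random lists at -1.12 (full range -2.69 to -0.24 over 4 members). Handling on the day and the operation itself cannot be told apart with 1 library per group.

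Haemoglobin RNA was at 6558 CPM in endothelial-like cells of the TAC library and at 192 CPM in its fibroblast-like cells, a ratio of 34.1, which argues against free RNA alike in every droplet as the whole source. The 31 endothelial cells with the most haemoglobin UMIs, the top 5%, held 93.9% of them, so red cells, or fragments of them, caught with a few endothelial cells may be the source of most. Without the UMIs of the top 5% the classes were at 402 and 161 CPM, a ratio of 2.501. The fall to that ratio follows from the 93.9% held by those cells, so it is no separate support. Of TAC cells in the compared classes, 86.9% to 89.1% held a haemoglobin UMI, with a median of 2 or 3. Those shares go with free RNA in the other cells. The TAC/sham list median of 5.64 in endothelial cells was 1.90 when the libraries were clustered separately. Whether red cells remained because of the surgery or of the lysis step was not tested.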
